A study of Mus musculus with 768 samples.

How the data were processed

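Single nuclei of mouse striatum were sequenced from 768 wells, 384 per genotype. The animals were untreated C57BL/6 mice carrying H2BG together with either Oprm1-Cre, chosen to include neurons of the patches (striosomes), or Slc32a1-Cre, chosen for GABAergic neurons. The deposited values are whole-number counts of reads per gene and well, and the authors gave them as 1 table per genotype and 1 joint table. All 18878976 values of the joint table were identical to those of the genotype tables. Each table holds 24489 genes by symbol, 92 spike-in transcripts and 1 reporter entry named eGFP. The build mm10 and the tools SAMtools and Seurat are named in the submitters' processing notes. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here. Per the labels' protocols the RNA came from a column kit and the libraries from a stranded total RNA kit with ribosomal depletion, which is a protocol for bulk RNA, so how each nucleus was amplified remains open. The counts carry no molecular identifiers, and PCR reads are not independent molecules, so intervals and floors below cover counting error only.

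Neither the labels nor the tables name animals, and each genotype fills a single plate of 16 by 24 wells. The labels of the Slc32a1-Cre samples name a count table under the plate number that the Oprm1-Cre table carries, while the Slc32a1-Cre table carries another number. Wells were therefore assigned by the column names of the tables, each of which ends exactly 1 sample title. A genotype was therefore treated as 1 sample, nuclei were not treated as replicates, and no p-value, standard error or number of changed genes was computed between genotypes. Plate, animals, their sex and genotype cannot be separated in this design. The design of each comparison, the filters, clustering settings, gene lists, class markers and the rule for named genes were fixed before the data were examined. The tests of explanations were chosen later, 3 of them after the result they address was seen. The limits of the class scores, the thinning depth and the minimum level for list members were set later, with the data in view.

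A well was kept with at least 1000 genes with a read and at least 20000 reads on genes, spike-ins and the reporter left out, which kept 355 nuclei of the Oprm1-Cre plate and 381 of the Slc32a1-Cre plate. Kept nuclei of both plates were clustered together on counts per 10000, log-transformed, with the 2000 most variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, seed 1). Clusters were named from fixed marker lists of spiny projection neurons (SPNs), interneurons, excitatory neurons, glia, vessel cells and ependymal cells. A cluster took another class than SPN when the mean log2(CPM + 1) of that class's markers lay more than 2 above the mean over all kept nuclei. The remaining clusters were SPN-like when the mean log2(CPM + 1) of 10 SPN markers was at least 3. Each SPN-like nucleus was D1-like or D2-like when the mean log2(CPM + 1) of 7 D1 markers (Drd1, Tac1, Isl1, Eya1, Slc35d3, Sfxn1, Ebf1) differed from that of 7 D2 markers (Drd2, Adora2a, Penk, Gpr6, Gpr52, Sp9, Grik3) by more than 2, and undecided otherwise. This gave 341 SPN-like nuclei in the Oprm1-Cre plate (299 D1-like and 24 D2-like) and 363 in the Slc32a1-Cre plate (194 and 149), and these numbers stand behind all shares and sums. The tables list Drd1 as Drd1a, and other older symbols were matched in the same way. No doublet caller was run. In 1 alternative, 34 possible doublets were left out, of which 8 were high for both SPN types, 11 carried markers of 2 classes and 15 were in the top 2% by genes with a read.

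Between genotypes, reads were summed per plate and class and given as CPM (counts per 1000000 reads of the sum) with exact Poisson 95% intervals. The log2 ratio of the Oprm1-Cre plate over the Slc32a1-Cre plate was taken with 5 CPM added to both, which understates the ratio of low genes. A list's median covers members with at least 5 CPM in either plate, and its percentile is among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Shares of nuclei have exact Clopper-Pearson 95% intervals, and shares with a read of a gene were taken after thinning each nucleus to 50000 reads. The lists were patch, matrix, eccentric or exopatch SPN, dorsolateral striatum, ventral or medial striatum, opioid system, dopamine and adenosine signalling, GABA synthesis and transport, ionotropic glutamate receptors, GABA-A receptors, muscarinic with serotonin and cannabinoid receptors, SPN potassium channels, Eph with ephrin, semaphorin and plexin, cadherins with protocadherins, immediate early genes, heat shock genes, mitochondrially encoded transcripts, nuclear-retained transcripts, sex-linked genes, and markers of astrocytes, oligodendrocytes, their precursors, microglia, vessel cells and excitatory neurons. Of the genes on these lists and among the markers, 14 are not analysed here because the tables hold no entry under their symbols, namely Tac3 and the mitochondrially encoded transcripts.

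D1-like and D2-like nuclei were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on 4 sums of reads, both classes in both plates, with plate as a term, TMM scaling and filterByExpr. The p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. This fit has 1 residual degree of freedom, moderated across genes, and its p-values measure only the spread between these plates. The class markers were left out of its counts.

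The rule for named genes took, between genotypes, the 12 genes with the largest log2 ratio each way in SPN-like nuclei. They needed at least 20 CPM and reads in at least 20% of the nuclei of the higher genotype, and the same direction in both SPN types and in both column sets (1 to 12 and 13 to 24) of the plates. Between D1-like and D2-like nuclei it took up to 12 genes each way past the threshold with at least 20 CPM in the higher class and the same direction in both plates. Members of the fixed lists could also be named. A called gene and the values of some markers are not reported here, and they remain in the counts and medians.

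The steps were tested on simulated data. In the comparison of D1-like with D2-like nuclei, over 13403 genes, 41% of 100 genes changed 4-fold and 73% of 100 genes changed 16-fold were recovered, with 8 false calls. All simulated sums came from 1 mean profile without a difference between plates, so these rates need not hold for the real plates. A first version of that simulation, with a single dispersion for all genes and smaller folds, recovered no changed gene, and it was replaced by a dispersion that follows expression and by these larger folds. For the log2 ratio between genotypes in D1-like nuclei, over 10469 genes, 200 genes changed 4-fold gave medians of 1.98 upward and -2.02 downward. That simulation held counting noise only and added far less than the 5 CPM of the reported ratios. It therefore does not show how closely the reported ratios recover a change.

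The alternatives varied the filter on nuclei, possible doublets, clustering resolution, the number of components, how classes were assigned, the weight of each nucleus, thinning, the scaling (TMM and DESeq2 size factors), the pseudocount, the minimum level, the plate columns used, equal weights for the SPN types, the removal of SPN-like clusters with an excess of eccentric SPN markers and the number of reads that count as detection. In the test they also varied the tool (DESeq2 1.42.0), the gene filter and the plate term. Added after seeing the data were clusters made without genes of chromosomes X and Y, the removal of the SPN-like cluster with the fewest reads, and each plate taken alone without a test. Gene positions come from the GENCODE M21 annotation of the mm10 assembly, and figures were drawn with matplotlib 3.10.9.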

Results

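Gene expression was measured in single nuclei of mouse striatum from 2 plates with 768 wells, 1 plate per Cre genotype. The Oprm1-Cre plate was meant to include neurons of the patches, the mu opioid receptor-rich compartment of the striatum that lies embedded in the matrix. The Slc32a1-Cre plate was meant to sample GABAergic neurons through the vesicular GABA transporter gene. After filtering, 29 wells of the Oprm1-Cre plate and 3 of the Slc32a1-Cre plate were left out. Kept nuclei held a median of 169398 reads on genes (range 22727 to 581313) in the Oprm1-Cre plate and 175337 (34513 to 487842) in the Slc32a1-Cre plate. The median number of genes with a read was 3761 and 3424, and spike-ins took a median of 23.9% and 22.2% of the reads. The wells left out of the Oprm1-Cre plate had at most 7313 reads on genes, with a median of 99.7% of reads on spike-ins, and those left out of the Slc32a1-Cre plate had at most 24598 reads and 951 genes. With 1 plate per genotype and no animals named, there were no replicates, so differences between genotypes are given as values without a test. The intervals beside them cover counting error only.

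Nearly all nuclei of both plates were SPN-like, that is, like the spiny projection neurons that form the output of the striatum. They made up 96.1% of the kept nuclei in the Oprm1-Cre plate (exact 95% interval 93.5% to 97.8%) and 95.3% in the Slc32a1-Cre plate (92.6% to 97.2%). The plates differed in the makeup of these neurons. D1-like nuclei, marked by the dopamine receptor gene Drd1 and the substance P precursor gene Tac1, formed 87.7% of the SPN-like nuclei in the Oprm1-Cre plate (83.7% to 90.98%) and 53.4% in the Slc32a1-Cre plate (48.2% to 58.7%). D2-like nuclei, marked by Drd2, the adenosine receptor gene Adora2a and the enkephalin precursor gene Penk, formed 7.04% (24 nuclei, 4.56% to 10.3%) and 41.1% (35.9% to 46.3%).

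The classes differ in their markers by definition. Median Drd1 in D1-like nuclei was 1704 CPM in the Oprm1-Cre plate and 1903 CPM in the Slc32a1-Cre plate, with median Penk at 6.5 and 12.6 CPM. In D2-like nuclei median Penk was 15053 and 16316 CPM, median Adora2a 1485 and 1595 CPM, and median Tac1 0 CPM in both plates. A further 5.28% (18 nuclei) and 5.51% (20 nuclei) of the SPN-like nuclei were undecided, and 15 and 17 nuclei lay within 0.5 of a score limit. Interneuron-like nuclei made up 3.66% (13 nuclei, 1.96% to 6.18%) in the Oprm1-Cre plate and 4.2% (16 nuclei, 2.42% to 6.73%) in the Slc32a1-Cre plate. These shares depend on how classes were made, with 1.41% and 1.57% when each nucleus was classed alone, 0.85% in the Oprm1-Cre plate with clusters made without genes of chromosomes X and Y, and 7.67% in the Slc32a1-Cre plate with at least 100000 reads. Oligodendrocyte-like nuclei numbered 1 and 2. How nuclei were labelled and sorted into wells is not given in the sources used here, so these are shares of the nuclei that each genotype delivered.

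**Figure D1:**
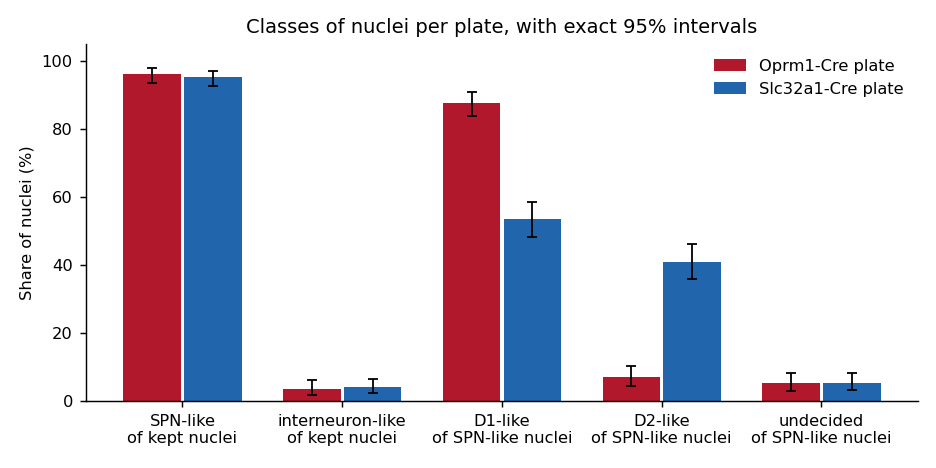
Share of nuclei (%) in each class per plate, as bars with exact 95% intervals for counting error. SPN-like and interneuron-like shares are of kept nuclei and the other shares are of SPN-like nuclei. The D2-like bar stands at 7.04% in the Oprm1-Cre plate and at 41.1% in the Slc32a1-Cre plate.

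The plates also differed in genes of the sex chromosomes. Reads of at least 1 of 4 Y-linked genes (Ddx3y, Uty, Kdm5d, Eif2s3y) were found in 90.99% of the kept nuclei of the Oprm1-Cre plate and in 0 nuclei of the Slc32a1-Cre plate, which allows a share of up to 0.96%. Xist, the RNA that coats the inactive X chromosome, had reads in 1.97% (7 nuclei) and 72.7% of the nuclei. The plates thus differed in the sex of the nuclei's donors as well as in genotype, and every comparison between genotypes carries both.

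Patch genes were higher and matrix genes lower in D1-like nuclei of the Oprm1-Cre plate than in D1-like nuclei of the Slc32a1-Cre plate. Of 13 measured members of the patch list, 11 had a log2 ratio above 0.5 and 0 had one below -0.5, with a median of 1.39 at percentile 100 of matched random lists. Of 9 matrix members, 6 lay below -0.5 and 0 above 0.5, with a median of -1.07 at percentile 0.0. In all SPN-like nuclei the patch median was 1.27, and 0.63 with D1-like and D2-like nuclei weighted alike. In D2-like nuclei the patch median was -0.51 (percentile 5.75) and the matrix median -0.43 (percentile 4.63), both inside the middle 95% of random lists. Of 12 patch genes measured there, 3 lay above 0.5, among them Sema5b (0.54), and 6 lay below -0.5. The D2-like sum of the Oprm1-Cre plate rests on 24 nuclei and 4125057 reads, against 29657302 reads in the other plate.

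Oprm1, which encodes the mu opioid receptor and gives the Oprm1-Cre genotype its name, was at 39.2 CPM (37.6 to 40.9) in D1-like nuclei of the Oprm1-Cre plate and 2.85 CPM (2.32 to 3.46) in those of the Slc32a1-Cre plate. Sema5b, a semaphorin gene, stood at 209.9 and 33.2 CPM, Kremen1 at 71.5 and 19.3 CPM, and Lypd1 at 43.4 and 11.6 CPM. The opioid peptide precursor gene Pdyn was at 1628 and 818.9 CPM and the orphan nuclear receptor gene Nr4a1 at 83.7 and 14.03 CPM. Rasgrp1 (log2 ratio 0.19) and Asic4 (-0.18) lay within 0.5 of no difference. Without Oprm1 itself the patch median in D1-like nuclei was 1.32, and without Tac1, which also served as a D1 marker, it was 1.47. Slc32a1 differed little, with 29.9 CPM in the Oprm1-Cre plate and 27.95 CPM in the Slc32a1-Cre plate. Oprm1 lies on chromosome 10 (6758506 to 7038198, plus strand of mm10), where it overlaps Ipcef1 on the opposite strand.

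Among matrix genes, the transcriptional regulator gene Id4 was at 22.3 CPM (21.1 to 23.6) in D1-like nuclei of the Oprm1-Cre plate and 155.3 CPM (151.2 to 159.4) in those of the Slc32a1-Cre plate. The ephrin receptor gene Epha4 was at 177.5 and 450.2 CPM, the calcium-binding protein gene Calb1 (calbindin) at 308.6 and 775.3 CPM and the synaptic vesicle protein gene Sv2b at 137.5 and 365.8 CPM. Gda (0.22), Rasgrp2 (-0.35) and Ebf1 (-0.35), the last of them also a D1 marker, lay within 0.5 of no difference on the log2 scale. In D2-like nuclei Sv2b (-1.81) and Epha7 (-1.37) were lower in the Oprm1-Cre plate, while Epha4 stood at 470.8 and 488.2 CPM. Id4, on chromosome 13 (48261228 to 48266026), overlaps the antisense gene A330033J07Rik, so reads of the pair cannot be told apart without strand.

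**Figure D2:**
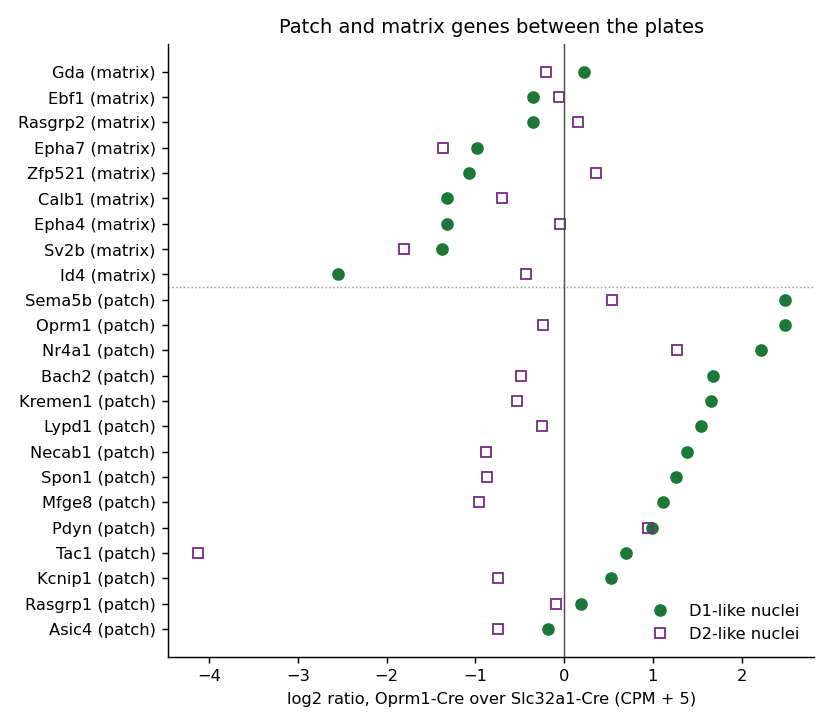
Log2 ratio of the Oprm1-Cre plate over the Slc32a1-Cre plate (5 CPM added) for each patch and matrix gene, in D1-like nuclei (filled circles) and D2-like nuclei (open squares). In D1-like nuclei the patch genes run from -0.18 for Asic4 to 2.49 for Sema5b and Oprm1, and the matrix genes from -2.55 for Id4 to 0.22 for Gda.

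The D1-like nuclei of the plates lay largely in different clusters, most often in cluster 0 for the Oprm1-Cre plate and in cluster 1 for the Slc32a1-Cre plate. A cluster mostly of 1 plate cannot be told apart from that library, so the contrast was also described nucleus by nucleus. The mean log2 level of 12 patch genes minus that of 8 matrix genes had a median of 1.18 in the D1-like nuclei of the Oprm1-Cre plate (mean 0.77, SD 2.16 over nuclei) and -2.73 in those of the Slc32a1-Cre plate (mean -2.49, SD 2.04). In D2-like nuclei the medians were -2.00 and -2.88, a smaller gap in the same direction. The upper quartile of D1-like nuclei in the Slc32a1-Cre plate (-1.49) lay below the lower quartile in the Oprm1-Cre plate (-0.85), while the full ranges of D1-like nuclei ran from -4.97 to 5.53 in the Oprm1-Cre plate and from -6.86 to 4.53 in the Slc32a1-Cre plate.

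**Figure D3:**
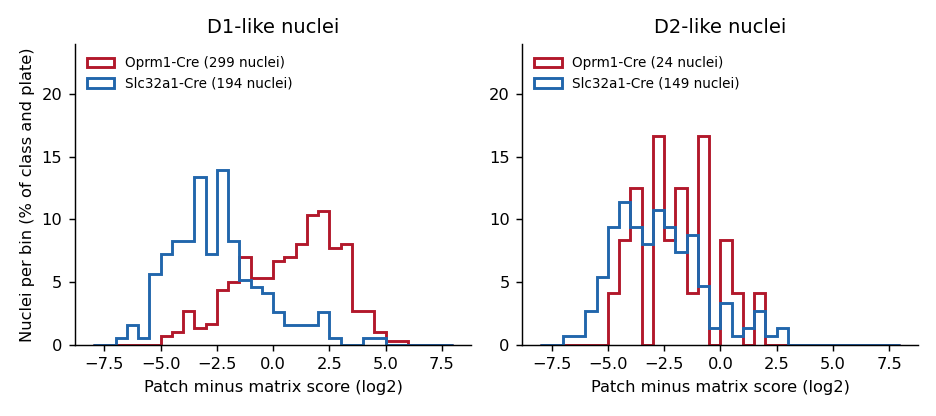
Patch minus matrix score (log2) on the horizontal axis and the share of nuclei per bin (% of class and plate) on the vertical axis, for D1-like nuclei on the left and D2-like nuclei on the right. Lines show the Oprm1-Cre plate, with 24 D2-like nuclei, and the Slc32a1-Cre plate. The D1-like distributions are centred at medians of 1.18 and -2.73.

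The same contrast appeared in the share of SPN-like nuclei with a read of a gene, after thinning each nucleus to 50000 reads, which left out 4 nuclei of the Oprm1-Cre plate and 1 of the Slc32a1-Cre plate. Oprm1 reads were present in 26.4% (89 nuclei, 21.8% to 31.5%) of the SPN-like nuclei of the Oprm1-Cre plate and 4.42% (16 nuclei, 2.55% to 7.08%) of those of the Slc32a1-Cre plate, and in 30.2% and 4.41% without thinning. Shares after thinning were 59.1% and 13.5% for Sema5b, 31.8% and 9.94% for Kremen1, 45.4% and 16.6% for Lypd1, and 83.7% and 37.8% for Pdyn. For the matrix genes they were 14.5% and 45.03% for Id4, 40.7% and 72.9% for Epha4, 62.02% and 78.5% for Calb1, and 32.9% and 58.01% for Sv2b. Without thinning they were 63.6% and 16.5% for Sema5b, 36.95% and 11.6% for Kremen1, 51.6% and 20.9% for Lypd1, 90.9% and 44.6% for Pdyn, 16.4% and 47.7% for Id4, 44.6% and 79.1% for Epha4, 64.8% and 82.4% for Calb1, and 39% and 64.5% for Sv2b.

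As background, Pdyn reads were found in 8.33% (2 of 24) and 9.4% (14 nuclei) of D2-like nuclei after thinning and in 45.8% and 20.1% without it. Unthinned, Npy reads, which belong to a class of interneurons, were found in 9.38% of the SPN-like nuclei of the Oprm1-Cre plate and 10.7% of those of the Slc32a1-Cre plate, and Sst reads in 26.7% and 35.3%. These genes are far more abundant in the nuclei that make them than Oprm1, so they set no background level for Oprm1, and whether its reads in the Slc32a1-Cre plate exceed background was not tested. In the Oprm1-Cre plate, thinned Oprm1 shares were 28.3% of D1-like nuclei (84 nuclei, 23.2% to 33.8%) and 12.5% of D2-like nuclei (3 of 24, 2.66% to 32.4%). These intervals overlap, but the summed level differed more. Oprm1 was at 39.2 CPM in D1-like and 2.7 CPM in D2-like nuclei of that plate. In the Slc32a1-Cre plate it was at 2.8 and 4.0 CPM. The D2-like level of the Oprm1-Cre plate rests on the 3 nuclei with reads.

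Most measured genes of the ventral or medial striatum and of eccentric or exopatch SPNs were also higher in D1-like nuclei of the Oprm1-Cre plate. Cluster 4, whose leading genes include Dlk1 and the eccentric SPN marker Otof, held 43 D1-like nuclei of the Oprm1-Cre plate and 3 of the Slc32a1-Cre plate. The summed reads cannot tell a larger share of that cluster from a shift in all D1-like nuclei. Of 6 measured ventral or medial genes, 4 lay above 0.5 and 0 below -0.5, with a median log2 ratio of 1.49 (percentile 100). Examples were Dlk1 at 27.5 and 3.9 CPM and the thyrotropin-releasing hormone receptor gene Trhr at 21.2 and 2.53 CPM, which rest on few nuclei, as Dlk1 reads were found in 11% and 3.1% and Trhr reads in 5% and 1.5% of the D1-like nuclei. Over all SPN-like nuclei the median of this list was 1.13 and ran from 0.49 to 1.32 over the alternatives. Lypd1 is on this list and on the patch list. Of 5 measured eccentric SPN genes, 4 lay above 0.5 with a median of 1.38 (percentile 100), among them Tshz1 (1.38) and Cacng5 (1.47). Over all SPN-like nuclei this list's median was 0.40, inside the range of random lists (-0.36 to 0.47), with 2 of 6 genes above 0.5, and it ran from 0.02 to 1.09 over the alternatives. In D2-like nuclei the medians of these lists were -0.42 and 0.27. The 5 dorsolateral striatum genes had a median of -0.12 in D1-like nuclei, with 2 below -0.5 (Gpr155 at -1.58 and Coch at -1.22).

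Lists of transmitter signalling differed less. In D1-like nuclei the median log2 ratios were 0.32 for 5 measured opioid genes, 0.13 for 11 dopamine and adenosine signalling genes, 0.08 for 5 genes of GABA synthesis and transport and 0.01 for 11 ionotropic glutamate receptor genes. They were -0.24 for 12 GABA-A receptor genes, 0.03 for 9 muscarinic, serotonin and cannabinoid receptor genes and -0.02 for 15 potassium channel genes. For adhesion and guidance genes they were 0.08 for 19 Eph, ephrin, semaphorin and plexin genes and -0.11 for 17 cadherin and protocadherin genes, and members went both ways. On the guidance list, 8 members lay above 0.5, among them Epha5 (1.03), and 6 below -0.5, among them Efna5 (-1.54). On the cadherin list, 3 lay above 0.5, among them Cdh18 (1.37), and 7 below -0.5, among them Pcdh11x (-2.35). All 9 of these medians lay between percentiles 9.38 and 95.6 of matched random lists.

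Some lists that follow handling and RNA quality also stood apart from random lists. Immediate early genes, which respond to recent neuronal activity, had a median log2 ratio of -0.45 in D1-like nuclei (percentile 0.03, 14 measured) and -0.74 in D2-like nuclei (percentile 0.43). Fos was at 0.58 CPM in D1-like nuclei of the Oprm1-Cre plate and 16.1 CPM in those of the Slc32a1-Cre plate, and Npas4 at 14.1 and 22.1 CPM. Nr4a1, on this list and on the patch list, went the other way with 2.22. The 4 measured heat shock genes had medians of -0.33 in D1-like nuclei (percentile 8.16, inside the random range) and -0.74 in D2-like nuclei (percentile 1.22). Nuclear-retained transcripts had medians of 0.50 in D1-like nuclei (percentile 99.8) and 0.48 in D2-like nuclei (percentile 96.6, inside the random range), among them Malat1 at 72504 and 50959 CPM in D1-like nuclei. Of the 6 sex-linked genes, 4 were higher and Xist lower in the Oprm1-Cre plate, while reads of Tsix, on the opposite strand of Xist, cannot be told apart from those of Xist without strand.

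Markers of other cells were low in the SPN-like sums. In D1-like nuclei the median log2 ratio was 0.14 for 5 measured astrocyte markers and -0.21 for 5 oligodendrocyte markers. It was 1.32 for 3 markers of oligodendrocyte precursors, of which Vcan (70.1 and 22.8 CPM) and Pdgfra (7.52 and 0.03 CPM) lay above 0.5 and Olig1 (-0.42) did not. In D2-like nuclei the astrocyte median was -0.62 and the oligodendrocyte median -1.76 (percentile 0.04), while Vcan was the only measured precursor marker (-0.25). No vessel or excitatory neuron marker reached 5 CPM in these sums. The mitochondrially encoded transcripts were not measured.

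The rule for named genes took 12 genes higher in SPN-like nuclei of the Oprm1-Cre plate. They were the 4 Y-linked genes, with Eif2s3y at 228.45 CPM against 0 reads (at least 5193-fold higher, from 3 reads over the group), followed by Fbn2 (log2 ratio 2.58), Chd7 (2.54), Pla2g4e (2.15), Sema5b (2.13), Zp3r (1.96), Gpc6 (1.87), Ipw (1.80) and Plekhh2 (1.78). Fbn2, which encodes the matrix protein fibrillin-2, was at 31.5 CPM (30.15 to 32.96) and 1.1 CPM (0.87 to 1.38), and Chd7, a chromatin remodeller gene, at 37.1 CPM (35.6 to 38.6) and 2.26 CPM (1.92 to 2.64). In D2-like nuclei Fbn2 had 5 and 0 reads, so its direction there rests on few reads.

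The 12 genes lower in the Oprm1-Cre plate were Xist (-7.94), the D2 markers Gpr6 (-3.28), Gpr52 (-2.59) and Drd2 (-2.53), Ptprm (-2.33), Id4 (-2.21), Pcdh11x (-2.03), Gpx6 (-1.92), Cap1 (-1.82), Cdh7 (-1.73), Ddit4l (-1.71) and Fam163b (-1.70). With D1-like and D2-like nuclei weighted alike, the log2 ratios of Gpr52 and Drd2 were -0.08 and -0.15, as both follow the share of D2-like nuclei, while that of Gpr6 was -0.93 (442.9 and 852.7 CPM in D2-like nuclei). Cap1, an actin regulator gene, was at 58.1 and 208.9 CPM in D1-like nuclei and 78.1 and 250.4 CPM in D2-like nuclei. The cadherin gene Cdh7 was at 18.98 and 87.1 CPM in D1-like nuclei and 27.6 and 77.2 CPM in D2-like nuclei. Cap1 overlaps Ppt1, and Pcdh11x overlaps H2afb3, on opposite strands, so reads of these pairs cannot be told apart without strand.

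The median log2 ratio over all measured genes was 0.01 in SPN-like, 0.0 in D1-like and -0.065 in D2-like nuclei. Across 7453 genes, which are not independent replicates, the ratio in D1-like nuclei correlated with that in D2-like nuclei with a Pearson r of 0.25 and a Spearman rho of 0.23.

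D1-like nuclei were compared with D2-like nuclei within both plates to describe the SPN types that the marker genes define. Outside the class markers, 4 of 13788 tested genes were higher in D1-like nuclei and 5 were higher in D2-like nuclei (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Higher in D1-like nuclei were Pdyn, the muscarinic receptor gene Chrm4, Lingo2, which encodes a leucine-rich repeat membrane protein, and the acid-sensing channel family gene Asic4. Among those higher in D2-like nuclei were Plxdc1, Nt5e, which encodes the ectonucleotidase that makes adenosine, Nell1 and the soluble guanylate cyclase subunit gene Gucy1a3. All 9 genes went the same way in both plates.

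Pdyn had a fitted log2 fold change of 6.85 (SE 0.236, edgeR adjusted p = 0.000118), from 1628 against 16 CPM in the Oprm1-Cre plate and 818.9 against 5.93 CPM in the Slc32a1-Cre plate. Chrm4 was at 221.3 and 176.8 CPM in D1-like nuclei, with 3 reads (0.73 CPM, 0.15 to 2.13) and 5 reads (0.17 CPM, 0.05 to 0.39) in D2-like nuclei (edgeR adjusted p = 0.00165). Lingo2 was at 57.7 and 149.98 CPM, with 1 read (0.24 CPM, 0.01 to 1.35) and 3 reads (0.10 CPM, 0.02 to 0.30) in D2-like nuclei (edgeR adjusted p = 0.00696). Asic4 was at 105.5 and 120.4 CPM against 1.70 and 6.17 CPM (edgeR adjusted p = 0.0491). With 5 CPM added, the log2 ratios in the Oprm1-Cre and Slc32a1-Cre plates were 5.30 and 5.14 for Chrm4, 3.58 and 4.93 for Lingo2 and 4.04 and 3.49 for Asic4.

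Among the genes higher in D2-like nuclei, Plxdc1 was at 6.27 against 137.45 CPM (126.4 to 149.2) in the Oprm1-Cre plate and 5.75 CPM against 5546 reads (CPM interval 182.11 to 191.99) in the Slc32a1-Cre plate (log2 fold change -4.79, SE 0.36, edgeR adjusted p = 0.00659). Nt5e (-3.48, SE 0.329) and Nell1 (-4.91, SE 0.463) both had an edgeR adjusted p of 0.0224. Gucy1a3 was at 121.6 against 424.0 CPM and 165.1 against 633.1 CPM (-1.93, SE 0.188, edgeR adjusted p = 0.025). Nell1, on chromosome 7 (49974864 to 50866608), overlaps the antisense gene Nell1os.

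**Figure D4:**
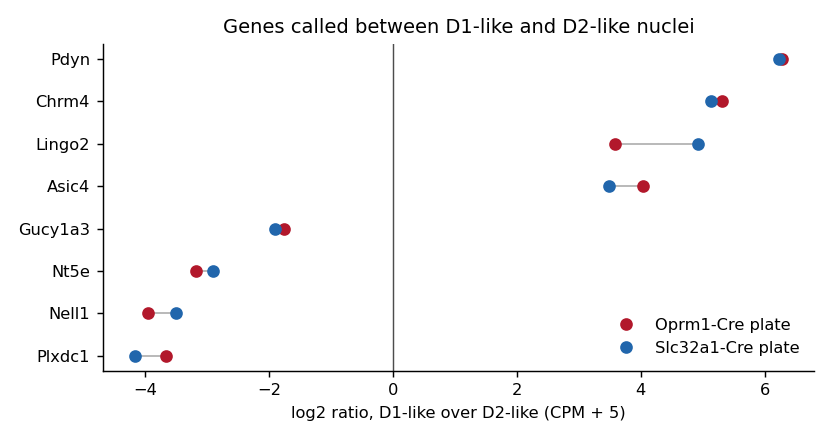
Log2 ratio of D1-like over D2-like nuclei (5 CPM added) for 8 genes past the threshold, 1 point per plate. Chrm4 stands at 5.30 and 5.14, Plxdc1 at -3.66 and -4.16, and every gene lies on the same side of 0 in both plates.

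By list, the patch list had 2 of 13 tested genes past the threshold over all genes, both higher in D1-like nuclei (Asic4 and Pdyn). Adjusted over the list alone, Necab1 was also lower in D1-like nuclei (-2.18). The opioid list had 1 of 6 over all genes (Pdyn), and adjusted over the list alone also Oprd1, the delta opioid receptor gene (-4.26, 2.34 against 34.2 CPM and 1.02 against 24.1 CPM). The list of muscarinic, serotonin and cannabinoid receptors had 1 of 12 over all genes (Chrm4). Adjusted over the list alone, Chrm3, Htr4 and Htr7 were also called, higher in D2-like nuclei. Htr7 had 0 reads in D1-like nuclei of both plates and reads in 4.2% and 1.3% of the D2-like nuclei, and it was called on the eccentric SPN list in the same way.

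The other lists had 0 genes past the threshold over all genes. Adjusted over the list alone, 1 gene was higher in D1-like nuclei on the ventral or medial list (Wfs1, 1.03), among nuclear-retained transcripts (Neat1, at 9.91 and 4.3 CPM against 0 reads) and among astrocyte markers (Slc1a3, at 15.1 and 13.2 CPM against 0 and 0.44 CPM). The GABA synthesis and transport list had 1 gene higher in D2-like nuclei (Gad1, -0.61). Adjusted over the list alone, no gene was called on the matrix, dorsolateral, dopamine and adenosine, ionotropic glutamate receptor, GABA-A receptor, potassium channel, guidance, cadherin, immediate early, heat shock or sex-linked lists, nor among the oligodendrocyte, precursor, microglia and excitatory neuron markers. At an unadjusted p under 0.05, 582 genes passed in edgeR, fewer than the 689 that chance alone would give among 13788, and DESeq2 called 67 genes higher in D2-like nuclei and a larger number higher in D1-like nuclei, among them all 9. In wells of plate columns 13 to 24 alone, edgeR called 0 genes.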

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

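Of the tests in this part, the comparison of patch genes in D2-like nuclei was chosen after the result was seen, and those of correlation with the patch minus matrix score were chosen before their results were known.

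Reads of the eGFP entry, which none of the comparisons used, appeared in 37.2% of the kept nuclei of the Oprm1-Cre plate (32.1% to 42.4%, 959 reads) and in 27.6% of those of the Slc32a1-Cre plate (23.1% to 32.3%, 810 reads). None of the 32 wells left out for too few reads or genes had such reads. Those wells held 22834 and 25157 reads on genes in total, too few to judge background.

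Several log2 ratios had opposite signs in the groups compared, and for the single genes these differences were not tested. The patch list had a median log2 ratio between genotypes of -0.51 in D2-like and 1.39 in D1-like nuclei. The D2-like median lay inside the range of random lists (-0.61 to 0.41), so an opposite effect on the patch list is not established. The patch minus matrix score of D2-like nuclei was higher in the Oprm1-Cre plate (medians -2.0 and -2.88). That score subtracts matrix genes, whose median log2 ratio in D2-like nuclei was -0.43, so it cannot settle the direction of the patch list. The channel subunit gene Cacng5 stood at 1.47 in D1-like and -2.29 in D2-like nuclei, where it had 6 reads in the Oprm1-Cre plate, and the cadherin gene Cdh4 at -1.11 and 2.29. Nnat had a log2 ratio of D1-like over D2-like nuclei of 1.22 in the Oprm1-Cre plate and -1.06 in the Slc32a1-Cre plate, and a fitted log2 fold change of -0.01 (edgeR adjusted p = 1.0).

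Patch genes were higher in D1-like nuclei of the Oprm1-Cre plate, and 13 other named genes, apart from those on the patch and matrix lists, class markers and genes of chromosomes X and Y, differed in SPN-like nuclei. An equal shift of the patch genes in every nucleus of a plate, from library preparation, sequencing or sex, would move D2-like nuclei alike. This was checked with 6 patch genes (Kremen1, Sema5b, Lypd1, Rasgrp1, Mfge8, Spon1). They had a log2 ratio between the types within 1 of 0 in the Slc32a1-Cre plate and at least 5 CPM in either plate in both types. Their median log2 ratio was -0.39 in D2-like against 1.40 in D1-like nuclei, with SDs over the 4 column sets of the plates of 0.94 and 0.54. The D2-like value is sparse, with Kremen1 reads in 2 of 24 and Lypd1 and Mfge8 reads in 5 of 24 nuclei of the Oprm1-Cre plate. Sema5b reads were in 37.5% of those nuclei against 12.75% in the Slc32a1-Cre plate, without thinning. The comparison therefore cannot decide on a shift that differs between the types. A different mix of patch-like and matrix-like nuclei remains a hypothesis. Under it, the named genes should follow the patch minus matrix score within each plate, and over the D1-like nuclei of the Slc32a1-Cre plate the 7 other genes higher in the Oprm1-Cre plate had a median correlation at percentile 100 of matched random lists (6 genes measured, r = 0.16), and 6 other lower genes one at percentile 0.0 (r = -0.19). Within the Oprm1-Cre plate the percentiles were 100 (r = 0.09) and 0.81 (r = -0.10), and a shift confined to D1-like nuclei of a plate, the animals and their sex stay open, since each genotype has 1 plate.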

How the results depend on the processing

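No paired analysis was possible because the genotypes share only well numbers, which pair nothing, and their comparison has no test, while the SPN types were compared with plate as a block. Clusters without genes of chromosomes X and Y, the removal of the cluster with the fewest reads and the plates taken alone were chosen after seeing the data. D2-like shares of called nuclei in the Oprm1-Cre plate ran from 6.45% to 7.69% over the alternatives with all plate columns. In the Slc32a1-Cre plate they ran from 39.4% to 44.1%. In columns 1 to 12 alone the shares were 8.12% and 44.83%, and in columns 13 to 24 they lay inside these ranges. In D1-like nuclei the patch median ran from 1.0 to 1.59 and the matrix median from -1.34 to -0.92. All 450 values of 25 named genes kept their direction and 33 moved, and of 490 values of 26 list medians 39 moved by more than 1 SD over the 4 column sets of the plates. The rule for named genes already required the same direction in both SPN types and both column sets. Alternatives on plate columns or equal weights for the types therefore could not reverse a gene taken by it. Signs changed in 23 of the 490 values, 22 of them for the 15 medians that lay within the middle 95% of random lists. The cause was not tested for the changes below unless stated. With clusters made without genes of chromosomes X and Y, the Oprm1-Cre plate was 99.2% SPN-like and 0.85% interneuron-like, as the nuclei with Th and Trh reads joined an SPN-like cluster. Classed nucleus by nucleus, interneuron-like shares were 1.41% and 1.57%, and the Slc32a1-Cre plate was 98.2% SPN-like. With at least 100000 reads that plate was 92.3% SPN-like and 7.67% interneuron-like. With 5 reads required, which raises the limit by construction, Oprm1 was found in 10.98% and 1.66% of SPN-like nuclei. The patch median in D1-like nuclei was 1.0 with 20 CPM added, which shrinks ratios by construction. The matrix median in D2-like nuclei was -0.21 with no minimum CPM and -0.61 in columns 1 to 12. The guidance list in SPN-like nuclei reversed from 0.25 to -0.00 with each nucleus weighted alike. Between the SPN types, 4 genes were higher in D1-like nuclei (0.0290% of 13788 tested) and 5 in D2-like nuclei (0.0363%). These became 2 (0.0144%) and 2 (0.0144%) with classes by cluster majority, with 3 of the 9 shared, 0 and 0 in columns 13 to 24, 18 (0.143%) and 16 (0.127%) after thinning, 12 (0.0701%) and 10 (0.0584%) without a gene filter and 1 (0.00725%) and 1 (0.00725%) without the plate term. DESeq2 called 0.810% of its 14935 tested genes higher in D1-like and 0.449% (67 genes) higher in D2-like nuclei. Genes higher in D2-like nuclei numbered 3 (0.0219%) with at least 100000 reads and 2 (0.0156%) in columns 1 to 12. All 9 genes kept their direction in every alternative. Depth limits the D2-like sum of the Oprm1-Cre plate, with 4125057 reads, and the interneuron-like sums, from 13 and 16 nuclei.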

Other observations

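The tests in this part on undecided nuclei and on free Th and Trh RNA were chosen after the results were seen, and the test with thinned nuclei was chosen before.

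The interneuron-like nuclei held a cluster led by Kit and a cluster led by Sst and Npy, with 10 and 3 nuclei in the Oprm1-Cre plate and 11 and 5 in the Slc32a1-Cre plate. Genes of the Kit-led nuclei were picked after their values were seen, and with clusters made without genes of chromosomes X and Y the 10 nuclei of the Oprm1-Cre plate joined an SPN-like cluster, so their class is not settled. All 10 Kit-led nuclei of the Oprm1-Cre plate had reads of both Th, the tyrosine hydroxylase gene, and Trh, the precursor gene of thyrotropin-releasing hormone (exact 95% interval 69.2% to 100%), and 0 of 10 had reads of Pthlh, a marker of the Pvalb and Pthlh interneurons. In the Slc32a1-Cre plate 2 of 11 had Th and Trh reads (18.2%, 2.28% to 51.8%), 8 of 11 had Pthlh reads (72.7%, 39.03% to 93.98%), and none had both. Summed Th was at 915.4 and 283.9 CPM, Trh at 3227 and 527.1 CPM, Htr3a at 414.6 and 223.8 CPM and Moxd1 at 0 and 848.4 CPM. In the cluster led by Sst and Npy, Npy was at 30049 and 28924 CPM and Sst at 23585 and 19891 CPM. Neither cluster had reads of Slc5a7, a marker of cholinergic interneurons. It had 407 reads in 4 SPN-like nuclei of the Oprm1-Cre plate and 1999 reads in 6 of the Slc32a1-Cre plate. The interneuron-like shares may therefore miss nuclei of that kind.

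Malat1, a transcript that stays in the nucleus, differed between the plates in SPN-like but not in interneuron-like nuclei. Rn45s, Meg3 and Miat were higher in the Oprm1-Cre plate in both classes. The interneuron-like sums rest on 13 and 16 nuclei. Their Th, Trh and Pthlh reads differed between the plates, so these sums do not compare like nuclei. Malat1 was at 71664 and 50199 CPM in SPN-like nuclei of the Oprm1-Cre and Slc32a1-Cre plates and at 29604 and 29625 CPM in interneuron-like nuclei. The ribosomal precursor Rn45s was at 13610 and 6523 CPM in SPN-like and at 13616 and 8744 CPM in interneuron-like nuclei, and Meg3 at 11387 and 7897 CPM in SPN-like and 13720 and 8026 CPM in interneuron-like nuclei.

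The Th and Trh reads of the Kit-led nuclei could come from free RNA in the wells of the Oprm1-Cre plate. Against this, Trh reads were found in 2.64% of that plate's SPN-like nuclei (9 nuclei, 1.21% to 4.95%), below the lower limit of 69.2% in the Kit-led nuclei. A difference in which interneurons the genotypes label, the region dissected and the animals stay open as untested explanations, with 10 and 11 nuclei behind the contrast.

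The share of D2-like nuclei was low in the Oprm1-Cre plate. Undecided nuclei are too few to close the gap. Together with the D2-like nuclei they made up 12.3% (42 nuclei, 9.02% to 16.3%) against a D2-like share of 41.1% (35.9% to 46.3%) in the other plate. This bound follows from the shares reported in the Results, and it does not show what the undecided nuclei are. If unequal reads per nucleus set the shares, thinning would bring them together, but the thinned D2-like share of called nuclei was 7.48% (24 nuclei, 4.85% to 10.9%) against 43.7% (38.4% to 49.1%). That Oprm1-Cre labels D1-like more often than D2-like neurons is a hypothesis that these data do not test, because genotype, plate, dissection and animals coincide.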
